A study of Homo sapiens with 4 samples.

How the data were processed

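RNA was measured by sequencing in 4 libraries of the human endometrial stromal line CRL-4003, all kept for 24 hours at 1% oxygen. The 2 ESF libraries came from undifferentiated stromal fibroblasts and the 2 DSC libraries from cells decidualized in culture, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were detached with trypsin, RNA was isolated with a column kit and libraries followed standard Illumina protocols. The agents and the length of decidualization and the strand setting of the counting are not given in the sources used here. The normoxic samples named in the series text are not analysed here.

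The deposited table holds whole-number counts of reads per Ensembl gene and, beside them, TPM values, per the file headers. Per the submitters' processing notes the tools were CASAVA 1.4, TopHat2 2.0.5 and HTSeq, with the genome build GRCh37; the notes give them no role or order, and the annotation release is not given in the sources used here. The deposited TPM were checked against the counts: over 11208 genes with more than 50 counts in every library, the ratio of count to TPM, scaled per library, gave a single length per gene to within 8.0e-12 of its value. How the authors defined gene length for the TPM is not given in the sources used here. Each column of values belonged to 1 sample and none was pooled. The table lists 60386 genes, of which 34811 had no count in any library, and 0 entries that name no gene. The reference at hand was of another build, so no coordinates are printed.

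Gene names were looked up by Ensembl ID in a current name table, which held 49489 of the IDs, and otherwise in GENCODE release 29. In all 49574 IDs (82.1%) had a name, and they held 99.5% of the counts. Of the 557 symbols in the gene lists, 5 matched no ID. As the counting is not stated to use strand, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies can exchange reads.

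Total counts were 32315801 and 41679065 in ESF and 38592717 and 32531575 in DSC. Counting intervals and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before they were averaged: over genes, the chi-square of their counts per degree of freedom was 14.5 in ESF and 4.22 in DSC, so neither pair was a single library deposited again. The 10 genes with the most counts took 17.7% to 19.0% of a library.

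Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10 and minimum total of 15, TMM normalization, and the quasi-likelihood test with cell state as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts over the TMM-scaled library total of the genes kept by the filter, times 1000000, and log2 fold changes are DSC over ESF. The SE of a log2 fold change is its size over the square root of the F statistic. Where a group had 0 to 3 counts, a lower bound against 3 counts over the group or a ratio with an exact 95% interval is given in place of the fitted change.

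The 31 gene lists, the design and the alternatives were fixed before the data were examined, and analyses added later are named as such. The lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a correlation between genes preset at 0.01, two-sided, with Benjamini-Hochberg adjustment over 28 lists. The same test with an estimated correlation and the rotation test fry were run beside it. With an estimated correlation camera uses only the residual degrees of freedom, few with 2 libraries per group, which by itself raises its p-values. Fry asks whether the genes of a list move on balance in a single direction, without reference to other genes. Members were also counted with the adjustment over the list alone.

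Genes were named by a rule with several parts. The 10 genes with the largest increase and the 10 with the largest decrease were taken among those called, with a mean log2 CPM of at least 4 and no overlap between the groups. From each list with 5 tested members, up to 2 higher and 2 lower members with the smallest adjusted p were taken. Named whatever their values were PRL, IGFBP1, FOXO1, HAND2, PGR, HIF1A, EPAS1, VEGFA, CA9, SLC2A1, LDHA, PDK1, MKI67, ACTA2 and COL1A1. This gave 119 genes. Other list members given in the text were chosen after their values were seen: CRYAB, DIO2, LEFTY2, ZBTB16, PPARGC1A, IGFBP3, IGFBP4, PAPPA, IGF1R, IGF2R, TYMS, LOX, PLOD2, SERPINE1, ANKRD37, IL33, MT1F and CGA.

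The procedure was tested on simulated data for this comparison, with counts for 14739 genes drawn from the libraries' means and totals, 200 of them changed, in 3 runs. It recovered 78.1% of changes of 1.5-fold, 98.0% of 2-fold and 100% of 4-fold, 5.64% of its calls were false, and 0 of 27 unshifted gene lists were called. The simulated genes were drawn independently of each other, and the changed ones were few and balanced in direction. The simulation therefore does not show how lists of correlated genes, or a change in most genes, would be called.

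Alternatives planned before the data were examined were the RLE size factors, library totals alone, no filter, a stricter filter (1 CPM in all libraries of a group and a mean count of 10), the replicate number as a block, DESeq2 1.42.0, limma on log2(TPM + 1) and on log2(TPM + 0.1) for the genes tested above, an adjusted p under 0.01, an added log2 fold threshold of 1, removal of ribosomal protein and mitochondrial genes, and each library left out in turn. With a group left at 1 library, that library was assumed to vary like the other group. Added after seeing the data were a crossed block, a likelihood-ratio test with a dispersion of 0.04 for every gene (a coefficient of variation of 0.2) and removal of the 10 genes with the most counts. On the scale of log2(TPM + 1), the changes of low genes are understated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.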

Results

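Messenger RNA was sequenced from the human endometrial stromal line CRL-4003, an established line immortalised with telomerase, after culture for 24 hours at 1% oxygen. Of the 4 libraries, 2 came from endometrial stromal fibroblasts (ESF), the undifferentiated form of the line, and 2 from decidual stromal cells (DSC), the same line decidualized in culture. Decidualization is the differentiation by which the stroma of the uterus prepares for pregnancy. The total counts per library were 32315801 and 41679065 in ESF and 38592717 and 32531575 in DSC. In these libraries 3 counts corresponded to between 0.0690 and 0.0955 CPM (counts scaled to a common library size). The series concerns how both cell states respond to low oxygen. The normoxic samples it refers to are not analysed here, so the comparison was DSC against ESF with both at low oxygen, and no response to oxygen was measured. The series text describes the libraries of a group as biological replicates. All come from a single cell line. The p-values set each difference against the spread between these libraries, which the test estimates for each gene with information shared across genes.

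Hypoxic DSC differed from hypoxic ESF in most of the genes measured. Of 18 tested decidualization markers, 14 were higher in DSC and 4 lower. Among those higher, HAND2, a transcription factor of the endometrial stroma, was 8.12-fold higher and FOXO1, a transcription factor of decidualization, 15.8-fold. The progesterone receptor PGR was 4.83-fold higher. Genes of cell division were lower, with all 24 tested genes of the G2 and M phases below their ESF level and the proliferation marker MKI67 32.6-fold lower. Several genes induced by hypoxia-inducible factors (HIF) were higher in DSC, among them ADM (adrenomedullin) by 5.76-fold and CA9 (carbonic anhydrase 9) by 9.98-fold, whereas the mRNA of HIF1A itself was 2.68-fold lower. All 6 tested metallothioneins, small metal-binding proteins, were higher in DSC.

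By edgeR's quasi-likelihood test, 10055 of 14739 genes (68.2%) passed an adjusted p under 0.05, of which 4961 were higher and 5094 lower in DSC (n = 2 libraries per group). Changes of over 2-fold were found in 1772 genes higher and 1475 lower, and changes of over 4-fold in 530 and 488. In 12263 genes (83.2%) both DSC libraries lay on the same side of both ESF libraries, where chance gives 33.3%. Among protein-coding genes 4105 were higher and 4734 lower, and among 417 tested long intergenic noncoding RNAs 180 were higher and 67 lower. The replicates differed little (a biological coefficient of variation of 0.0550), so small changes passed the test. With another test (likelihood ratio) and a coefficient of variation of 0.2 for every gene, both chosen after seeing the data, 4606 genes passed. The balance of directions depended on the scaling: 49.3% of the calls were higher in DSC with TMM scaling, 41.2% with library totals alone and 38.3% with limma on the deposited TPM. On the log2 scale the median of all genes was -0.11 under each of these last alternatives. The median of the shifts of single genes from the main analysis was -0.11 with library totals alone and -0.15 with limma on the TPM.

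**Figure D1:**
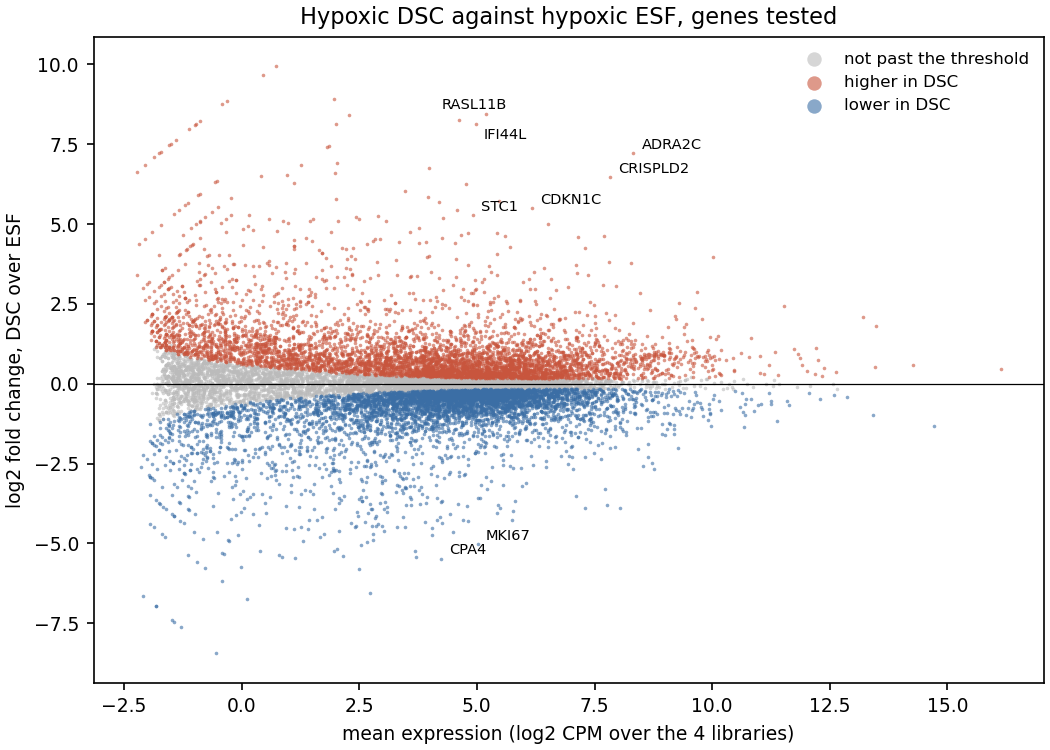
Log2 fold change of DSC over ESF (y axis) against mean log2 CPM over the 4 libraries (x axis), with 1 point per gene tested, red where higher and blue where lower in DSC at an adjusted p under 0.05 and grey otherwise. Coloured points fill both sides of 0, ADRA2C (log2 fold change 7.21) and MKI67 (-5.03) stand far from it, and the fitted changes at the far left, where a group holds few or no counts, depend on the prior count and are not sizes.

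Among genes with a symbol and a mean log2 CPM of at least 4, the largest increase was that of RASL11B (ENSG00000128045), a small GTPase of the Ras family, from 0.152 ± 0.0452 CPM in ESF to 49.4 ± 1.70 in DSC (SD, n = 2 each), a log2 fold change of 8.28 ± 0.17 (SE). IFI44L (ENSG00000137959), an interferon-inducible gene, followed with 0.213 ± 0.0890 CPM in ESF and 63.2 ± 1.52 in DSC. The alpha-2C adrenergic receptor gene ADRA2C (ENSG00000184160) rose to 638 ± 24.0 CPM from 4.31 ± 0.142, the highest level in DSC among these 10 genes, and CRISPLD2 (ENSG00000103196), which encodes a secreted protein, to 447 ± 3.69 from 5.06 ± 0.302. The cell cycle regulator RGCC, the growth factor PDGFD, the transporter ABCA8, the cyclin-dependent kinase inhibitor CDKN1C, the noncoding RNA LINC02600 and the secreted glycoprotein STC1 completed the 10, with log2 fold changes from 6.27 for RGCC to 5.29 for STC1. The adjusted p values of these genes in edgeR lay between 1.1e-19 for ADRA2C and 8.4e-17 for LINC02600. A gene without a symbol in the name sources used here, ENSG00000223414, lay above them all, at 0.215 ± 0.0771 CPM in ESF and 73.5 ± 2.69 in DSC (log2 fold change 8.44 ± 0.15).

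The largest decrease by the same rule was in CPA4 (ENSG00000128510), a carboxypeptidase, from 36.0 ± 2.96 CPM in ESF to 0.796 ± 0.135 in DSC (SD, n = 2 each; log2 fold change -5.48 ± 0.14 SE, adjusted p = 1.7e-16). MKI67 (ENSG00000148773) went from 62.1 ± 3.51 to 1.90 ± 0.0547 CPM, and FOXM1 (ENSG00000111206), a transcription factor of mitotic genes, from 52.3 ± 0.349 to 2.69 ± 0.249. CEP55, KIF20A, CDC20, BIRC5 and RRM2, which act in cytokinesis, mitosis or the supply of deoxynucleotides, lay between -4.75 and -4.26. The remaining members of the 10 were the serpin SERPINB7 (-4.38) and the cell adhesion gene NTM (-4.26).

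All 18 tested decidualization markers passed the test, 14 of them higher and 4 lower in DSC, with the same numbers adjusted over the list alone (median log2 fold change 1.68; adjusted p = 5.4e-04 by limma's camera, and adjusted p = 0.364 with an estimated correlation). Calls of lists given here are those of camera unless fry is named. Prolactin (PRL, ENSG00000172179), the classical secreted product of decidual cells, had 2 counts over both ESF libraries and 566 over both DSC libraries, a CPM ratio of 318 with a 95% counting interval of 87.6 to 2630. Its mean was 8.19 ± 1.37 CPM in DSC. IGFBP1 (ENSG00000146678), another decidual product, stayed low at 0.658 ± 0.0141 CPM in DSC against 0.0530 ± 0.00990 in ESF (log2 fold change 3.57 ± 0.51, adjusted p = 5.1e-06). HSD11B1, which regenerates cortisol from cortisone, was 57.7-fold higher, FOXO1 (ENSG00000150907) went from 1.84 ± 0.0981 to 29.2 ± 1.46 CPM and HAND2 (ENSG00000164107) from 26.9 ± 0.0279 to 219 ± 10.3. LEFTY2, with no count in ESF, was at least 71.1-fold higher against a floor of 3 counts over the group. The lower members were IL11 (-1.26), TIMP3 (-0.57), CRYAB (-0.55) and DIO2 (-0.50).

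Steroid receptors and targets of progestins or glucocorticoids were higher in 10 of 11 tested members and lower in 1, also when adjusted over the list alone (median 1.05; adjusted p = 1.0e-03, and adjusted p = 0.364 with an estimated correlation). PGR (ENSG00000082175) went from 13.0 ± 1.4 to 62.4 ± 2.65 CPM and the clock gene PER1 from 7.48 ± 0.109 to 53.3 ± 0.604. ZBTB16 had 3 counts in ESF and a CPM ratio of 25.5 (95% counting interval 8.35 to 126). The exception was the glucocorticoid receptor NR3C1 (-0.25 ± 0.08, adjusted p = 8.4e-03), whose adjusted p was 0.0971 without DSC replicate 1 and 0.0628 without DSC replicate 2. Of the 14 genes of the cAMP response, 9 were higher, 1 was lower and 4 did not pass the test, the same adjusted over the list alone (median 1.31; adjusted p = 4.4e-03, and adjusted p = 0.364 with an estimated correlation). The phosphodiesterases PDE4B (log2 fold change 3.29) and PDE4D (3.24), which degrade cAMP, were among the higher members, and PPARGC1A, with no count in ESF, was at least 15.7-fold higher. The lower member, the kinase regulatory subunit gene PRKAR2B (-0.81 ± 0.23), had an adjusted p of 0.0742 without DSC replicate 2.

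In the insulin and IGF axis 12 of 14 genes were higher in DSC, 0 were lower and 2 did not pass, and the numbers were equal adjusted over the list alone (median 1.84; adjusted p = 1.7e-05, and adjusted p = 0.364 with an estimated correlation). STC1 reached 59.2 ± 2.87 CPM from 1.53 ± 0.175. The insulin receptor substrate gene IRS2 rose 4.65-fold, to 351 ± 3.10 CPM. The IGF-binding protein genes IGFBP3 (log2 fold change 2.10) and IGFBP4 (2.43), and PAPPA (2.30), whose protein cleaves IGFBP4, also rose. The receptor genes IGF1R (0.14, adjusted p = 0.12) and IGF2R (0.04, adjusted p = 0.73) did not pass.

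Every tested gene of the S phase list (21) and of the G2 and M phase list (24) was lower in DSC, over all genes and adjusted over the list alone. The medians were -2.21 and -3.50, with adjusted p = 3.2e-10 and 1.5e-13 by camera, and adjusted p = 0.253 with an estimated correlation for both lists. Thymidylate synthase TYMS (-1.97), the ribonucleotide reductase subunit RRM2 (-4.26) and the replicative helicase subunit MCM5 (-2.83) stood for the S phase genes. TOP2A, the topoisomerase of dividing cells, went from 104 ± 4.98 to 8.05 ± 0.184 CPM. Of 7 tested replication-dependent histone genes, whose transcripts largely lack poly(A) tails, 4 were higher, 0 lower and 3 did not pass, also adjusted over the list alone. H2BC12 (1.31) and H2BC5 (1.95), which share sequence with other histone genes, were among the higher members. That list was not called (adjusted p = 0.0758; 0.0384 without ESF replicate 1).

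Of 29 tested HIF target genes outside glycolysis, 24 were higher in DSC, 1 was lower and 4 did not pass, the same adjusted over the list alone (median 0.73; adjusted p = 8.2e-06, and adjusted p = 0.288 with an estimated correlation). ADM rose from 187 ± 10.5 to 1077 ± 57.2 CPM (log2 fold change 2.53 ± 0.08, adjusted p = 2.8e-15), HILPDA, a lipid droplet protein gene, from 8.02 ± 0.269 to 48.7 ± 1.69, and CA9 (ENSG00000107159) from 0.345 ± 0.0643 to 3.53 ± 0.0876. VEGFA (ENSG00000112715), the vascular growth factor, differed by 0.33 ± 0.07 (325 ± 21.9 against 409 ± 16 CPM, adjusted p = 6.4e-04), a call that ended with limma on log2(TPM + 1), at 0.18 and an adjusted p of 0.0519. The lower member was STC2 (-0.51), and LOX, PLOD2, SERPINE1 and ANKRD37 did not pass.

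The glycolysis genes moved both ways: 9 of 22 were higher, 6 lower and 7 did not pass, with the same numbers adjusted over the list alone, and camera did not call the list against other genes (median 0.10, adjusted p = 0.372), while fry, which does not compare with other genes, called it higher (adjusted p = 4.8e-03). Its median was -0.01 with library totals alone, with 7 genes higher and 7 lower, and -0.05 with limma on the TPM, with 6 higher and 7 lower. PFKFB4 (log2 fold change 1.59), a regulator of glycolytic flux, and the glucose transporter SLC2A1 (ENSG00000117394; 362 ± 22 against 726 ± 13.1 CPM, 1.00 ± 0.07) were higher. Pyruvate kinase PKM (-0.89) and the phosphofructokinase PFKP (-0.74) were lower. LDHA (ENSG00000134333; -0.10 ± 0.08, adjusted p = 0.27) and PDK1 (ENSG00000152256; 0.08 ± 0.08, adjusted p = 0.37) did not pass; LDHA passed as lower with library totals alone (-0.21, adjusted p = 0.0234) and with limma on the TPM (-0.25, adjusted p = 0.0169). Of 9 tested genes of the oxygen sensing machinery 5 were higher, 1 was lower and 3 did not pass, equal adjusted over the list alone (median 0.18, adjusted p = 0.419). This balance depended on the scaling. With library totals alone 3 were higher and 2 lower (median 0.07), and with limma on the TPM 3 were higher and 3 lower (median 0.02). HIF1A (ENSG00000100644) fell from 314 ± 35.3 to 117 ± 3.70 CPM (-1.42 ± 0.08, adjusted p = 1.4e-11). EPAS1 (ENSG00000116016), which encodes HIF-2α, was at 101 ± 6.52 and 137 ± 4.84 CPM (0.43 ± 0.07, adjusted p = 3.2e-05). ARNT (0.73), the shared partner of both factors, and CITED2 (1.08), an inhibitor of HIF, were higher.

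**Figure D2:**
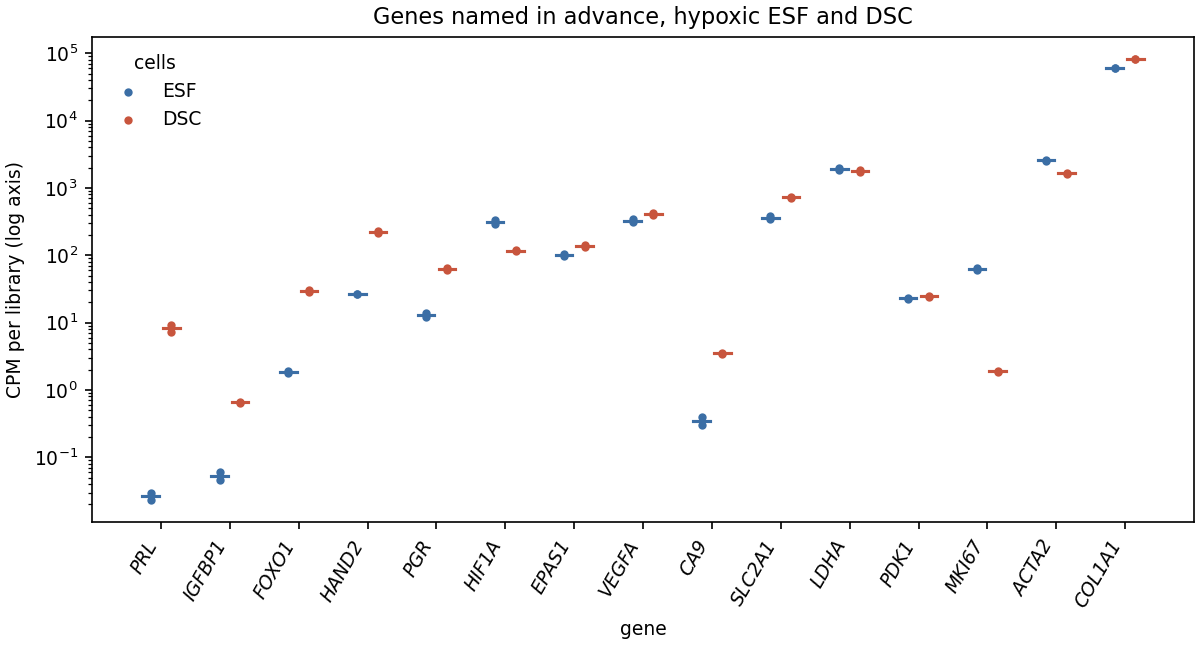
CPM per library on a log axis (y axis) for 15 genes chosen before the data were examined (x axis), with 1 point per library and a bar at the mean of the 2 libraries, ESF in blue and DSC in red. PRL, FOXO1, HAND2, PGR and CA9 lie higher in DSC and MKI67 and HIF1A lower, while LDHA and PDK1 differ by less than the test could call.

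The matrix genes were divided. In the interstitial matrix list 15 of 25 genes were higher, 9 lower and 1 did not pass, equal adjusted over the list alone, and the list was not called (median 0.45, adjusted p = 0.159). COL14A1 rose 24.7-fold and FBLN1, a fibulin, 5.89-fold. Fibronectin (FN1) went from 38634 ± 4275 to 15339 ± 913 CPM (-1.33 ± 0.10, adjusted p = 1.0e-09) and tenascin C (TNC) from 190 ± 3.62 to 66.1 ± 0.606. COL1A1 (ENSG00000108821), the gene with the most counts in each library, took 6.27% ± 0.0254 of the counts in ESF and 7.96% ± 0.0410 in DSC (0.45 ± 0.10, adjusted p = 4.4e-04); the call ended with limma on log2(TPM + 1) (0.30, adjusted p = 0.314). Basement membrane genes were higher in 12 of 19 tested members, lower in 4 and not called in 3, with 13 higher and 4 lower adjusted over the list alone (median 0.50; adjusted p = 9.1e-03, and adjusted p = 0.577 with an estimated correlation). The nidogen NID2 (2.25) and COL18A1 (1.87) were higher, and the laminin chains LAMB3 (-0.48) and LAMA1 (-0.39) lower.

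Contractile and YAP target genes were lower in 12 of 19 members, higher in 4 and not past the test in 3, equal adjusted over the list alone (median -0.47; adjusted p = 0.0369, and adjusted p = 0.364 with an estimated correlation). The call ended with library totals alone (adjusted p = 0.0505), with the stricter filter (0.0529) and without DSC replicate 2 (0.0588), over a range of 6.9e-03 to 0.364 across camera's alternatives. ANKRD1, a YAP target, fell 43.2-fold, the myosin light chain kinase MYLK 2.56-fold, and smooth muscle actin ACTA2 (ENSG00000107796) from 2564 ± 61.1 to 1658 ± 25.8 CPM (-0.63 ± 0.08, adjusted p = 7.6e-07). TGFBI (1.39) and ACTG2 (0.68) were higher.

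The 6 tested metallothioneins were all higher, also adjusted over the list alone (median 3.63; adjusted p = 5.4e-04, and adjusted p = 0.364 with an estimated correlation). MT1X went from 7.47 ± 0.420 to 79.6 ± 5.98 CPM and MT1E from 25.6 ± 2.39 to 112 ± 3.29; these genes are close copies, so the division of reads among them is uncertain. Of 20 antioxidant genes 11 were higher, 6 lower and 3 did not pass, equal adjusted over the list alone, with no call (median 0.26, adjusted p = 0.372). The excess of higher members depended on the scaling, with 10 higher and 8 lower with library totals alone (median 0.15). With limma on the TPM 8 were higher and 8 lower (median 0.10). Heme oxygenase HMOX1 rose 18.9-fold, to 298 ± 36.7 CPM, and catalase CAT 2.08-fold, while NQO1 (-1.34) and the peroxiredoxin PRDX6 (-1.17) fell. Heat shock genes were lower in 11 of 14 members, higher in 1 and not past the test in 2, equal adjusted over the list alone (median -0.67; adjusted p = 9.3e-03, and adjusted p = 0.364 with an estimated correlation), including the chaperones HSPH1 (-1.39) and DNAJA1 (-1.17). The higher member was HSPA4L (0.68). In the unfolded protein response list 6 of 20 were higher, 11 lower and 3 not called, with 12 lower adjusted over the list alone, and camera did not call the list (median -0.59, adjusted p = 0.0794), though it did with no filter (0.0208), as did fry (5.8e-03). TRIB3 (-2.63) and asparagine synthetase ASNS (-2.53), both targets of the transcription factor ATF4, were lower, and the chaperone genes PDIA6 (0.65) and HSP90B1 (0.52) higher.

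Senescence and p53 target genes were lower in 12 of 16 and higher in 4, equal adjusted over the list alone (median -0.53; adjusted p = 0.0441, and adjusted p = 0.364 with an estimated correlation). The call ended with library totals alone (adjusted p = 0.0853), the stricter filter (0.0596), without DSC replicate 1 (0.0506) and without DSC replicate 2 (0.0650), over a range of 0.0121 to 0.364 across camera's alternatives. The oxidoreductase gene TP53I3 fell 14.8-fold and the inhibitor CDKN2B 5.14-fold, while CDKN1C rose from 3.07 ± 0.273 to 141 ± 10.2 CPM and the lysosomal galactosidase GLB1 1.97-fold. Immediate early genes were lower in 10 of 15, higher in 3 and not past the test in 2, equal adjusted over the list alone, without a call by camera (median -0.56, adjusted p = 0.0807), though with a call with no filter (0.0311) and by fry (8.1e-03). EGR2 (-3.20) and KLF2 (-2.53) fell, and FOS (2.98) and MYC (1.00) rose.

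Of the 12 tested inflammatory genes 9 were higher, 2 lower and 1 did not pass, equal adjusted over the list alone (median 0.92; adjusted p = 0.0396, and adjusted p = 0.577 with an estimated correlation). The call ended with the stricter filter (adjusted p = 0.191) and without DSC replicate 1 (0.0639), over a range of 6.9e-03 to 0.577 across camera's alternatives. The chemokine CCL2 rose 3.34-fold and NFKBIA, an inhibitor of NF-kB, 1.97-fold; IL33, with no count in ESF, was at least 16.1-fold higher, at 0.622 CPM in DSC. The cytokine LIF fell 6.71-fold. TNFAIP6 was lower (-0.36 ± 0.11, adjusted p = 6.7e-03), with an adjusted p of 0.113 without DSC replicate 2. Interferon-stimulated genes went both ways, with 4 of 15 higher, 6 lower and 5 not past the test, equal adjusted over the list alone (adjusted p = 0.558). The median of that list was -0.34, with camera also pointing down, and its mean 0.50, with fry pointing up. IFI44L and IFI44 (3.20) were higher and XAF1 (-1.07) and STAT1 (-0.79), the transcription factor of interferon signalling, lower.

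Angiogenic ligands and receptors were higher in 8 of 16, lower in 6 and not past the test in 2, with 7 lower adjusted over the list alone, and were not called (median 0.07, adjusted p = 0.588; the median was -0.04 with library totals alone and -0.09 with limma on the TPM). The growth factors HGF (27.2-fold) and FGF7 (7.62-fold) were higher, and FGF1 (-1.77) and PDGFA (-1.62) lower. Of 15 WNT signalling genes 9 were higher, 4 lower and 2 did not pass, equal adjusted over the list alone (median 0.44, adjusted p = 0.135). The WNT median was 0.33 with library totals alone (9 higher, 5 lower) and 0.18 with limma on the TPM (8 higher, 5 lower). RSPO3, which enhances WNT signalling, rose from 0.0830 ± 0.0523 to 7.97 ± 0.338 CPM and WNT5A from 578 ± 37.2 to 1643 ± 23.1, while the transcription factor TCF7 fell from 2.04 ± 0.00481 to 0.113 ± 0.0696. Cholesterol synthesis genes (6 higher, 9 lower and 5 not past the test of 20, equal adjusted over the list alone; median -0.16, adjusted p = 0.437) included DHCR24 (-1.15) among the lower and the LDL receptor LDLR (0.63) among the higher members.

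Of the nuclear genes of oxidative phosphorylation 3 of 28 were higher, 10 lower and 15 not called, equal adjusted over the list alone (median -0.03, adjusted p = 0.417). With library totals alone 2 were higher and 12 lower (median -0.14), and with limma on the TPM 1 was higher and 14 lower (median -0.19). NDUFA9 (-0.84) and NDUFS1 (-0.69) were lower and NDUFA4 (0.38) and NDUFA2 (0.41) higher, the last not with limma on log2(TPM + 1) (0.26, adjusted p = 0.0545). Of the 13 mitochondrially encoded mRNAs 9 were lower, 0 higher and 4 did not pass, equal adjusted over the list alone (median -0.30, adjusted p = 0.0664 by camera; 0.0171 with no filter and 9.9e-04 without ESF replicate 1). MT-CO2 (-0.86) and MT-ND2 (-0.77) were among the lower. Together these mRNAs took 2.08% and 2.67% of the counts in the ESF libraries and 1.87% and 1.81% in the DSC libraries.

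Camera called no list of markers of other cell types. Of 8 tested epithelial genes 1 was higher, 4 were lower and 3 did not pass, equal adjusted over the list alone (median -0.84, adjusted p = 0.159; lower by fry, adjusted p = 0.0121): the keratins KRT18 (215 ± 11.4 against 43.8 ± 2.69 CPM) and KRT19 (-1.68) were lower and MUC1 (1.32) higher. Perivascular genes were higher in 6 of 9, lower in 2 and not called in 1, equal adjusted over the list alone (median 0.32, adjusted p = 0.361), with KCNJ8 (1.08) and MCAM (0.51) higher and CSPG4 (-1.71) and DES (-2.46) lower. Only 3 endothelial, 4 leukocyte and 4 trophoblast markers had enough counts to test, too few for a test of the list. Of these, 1, 1 and 2 were higher and 2, 0 and 2 lower, also adjusted over each list alone. Among them the gonadotropin subunit gene CGA had 2 counts in ESF and 83 in DSC, a CPM ratio of 46.6 (95% counting interval 12.5 to 391).

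**Figure D3:**
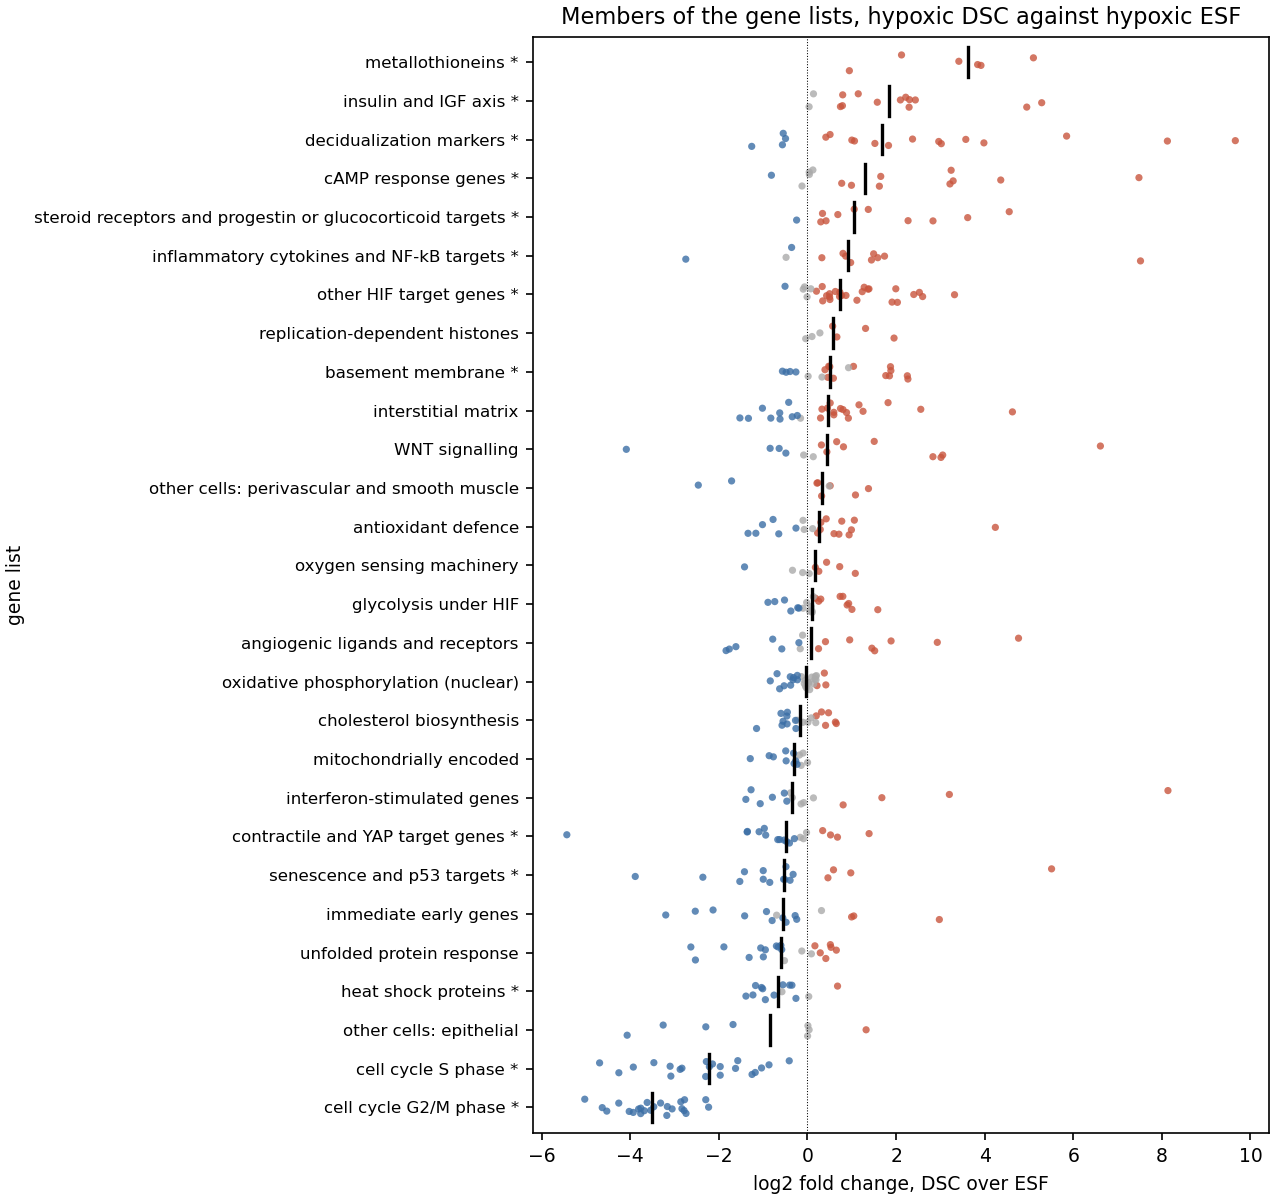
Log2 fold change of DSC over ESF (x axis) for each tested member of the 28 gene lists with at least 5 tested members (y axis), with 1 point per gene, red where higher, blue where lower and grey where not past the test, a black bar at the median and a star where camera called the list. The cell cycle lists lie wholly below 0 with medians of -2.21 and -3.50, and the metallothioneins wholly above 0 with a median of 3.63.

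Of 28 lists tested, camera called 8 higher and 5 lower with a preset correlation between genes, and 0 with a correlation estimated from the data (3 at an unadjusted p under 0.05), while fry called 22. The 9 lists that fry called and camera did not were glycolysis, interstitial matrix, the unfolded protein response, antioxidant defence, angiogenic genes, immediate early genes, histones, WNT signalling and epithelial markers, with adjusted p from 4.8e-03 to 0.0199. Of the genes named here that were chosen by rule, the calls for TIMP3, STC2, LAMB3, LAMA1, ACTG2, PDIA6, HSP90B1, TNFAIP6, NR3C1, PRKAR2B, LDLR, NDUFA2, NDUFA4, NDUFS1, HSPA4L, MCAM, EPAS1, VEGFA, ACTA2 and COL1A1 ended with the likelihood-ratio test at a coefficient of variation of 0.2.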

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

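Chosen only after the data were seen were the crossed pairing, the assumed coefficient of variation of 0.2 and the removal of the 10 genes with the most counts. The number of called genes, 10055, stayed between 8531 and 10725 under another normalization, filter, tool or unit, an adjusted p under 0.01, a block, and with gene classes left out, and 0 genes called in the main analysis and in an alternative changed direction. With single libraries left out it ranged from 8411 to 10080, the lowest without DSC replicate 1. Asking in addition for a log2 fold change above 1 left 3247 genes (1772 higher, 1475 lower), by the construction of that threshold. A likelihood-ratio test with a coefficient of variation of 0.2 for every gene left 4606 (2453 higher, 2153 lower), and the effects of the test and of the wider spread were not separated. Of 13 called lists, 0 passed with an estimated correlation (lowest adjusted p 0.253), and fry called 22; all 13 had the same direction in fry. With 2 libraries per group the estimated correlations rest on few residuals. They lay below the preset 0.01 for called lists such as S phase (-0.03), G2 and M phase (-0.03), HIF targets (-0.03), metallothioneins (-0.05) and cAMP response (-0.08). For others, such as basement membrane (0.44) and inflammatory genes (0.34), they lay above it. A higher correlation therefore does not account for the lost calls of the lists below the preset. With an estimated correlation camera uses only the residual degrees of freedom, which are few here and raise its p-values whatever the correlation. The lost calls thus cannot be read as an effect of correlation alone. Lists called numbered 10 to 16 under the other settings.

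The labels give both groups the same replicate numbers, but nothing says that they mark a shared day or culture, and there are only 2 pairs. Deviations of same-numbered libraries from their group means correlated across genes at -0.10 (Pearson, 14739 genes, which are not independent), and at -0.41 over the 7190 genes with a mean log2 CPM of 4 or more. With the replicate number as a block 9555 genes and 13 lists were called, and with the crossed pairing 10725 genes. Of the 119 named genes, 119 kept their call under the block. Depth limits the lowest genes: PRL, MT1F and CGA had 2 counts in ESF, so their ratios span wide intervals.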

Other observations

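The tests given here were chosen after the results they concern were seen, except those on pseudogene reads and on genes with a terminal oligopyrimidine tract, which were set before their results were seen. Of the former, the criteria for scaling of the HIF targets and for reads of IFI44L counted as IFI44 were also reworded once the results were known: for scaling, a call of the list was replaced by calls of its members, because camera compares a list with other genes, which the scaling moves too, and for IFI44 the part on ESF became a test of its own. The genes named here were likewise chosen after their values were seen. Genes of the amino acid response, largely targets of the transcription factor ATF4, were lower in DSC: of 23 such genes, listed after ASNS and TRIB3 had been seen, 20 were lower and 2 higher (median log2 fold change -1.13, and 20 lower and 1 or 2 higher under the other scalings). ASNS and TRIB3 are themselves among the 20 lower genes. STC2, CHAC1, SLC7A11, SESN2 and DDIT4 among the 23 also belong to the gene lists tested earlier, so their values were already at hand. PSAT1, an enzyme of serine synthesis, was lower by -3.31 ± 0.08 (SE), the amino acid transporter SLC7A5 by -2.30 ± 0.08 and the folate enzyme MTHFD2 by -1.95 ± 0.07, while the mRNA of ATF4 itself was at the threshold (0.17, adjusted p = 0.0497) and without a call under library totals alone (0.06, adjusted p = 0.485) or limma on the TPM (0.02, adjusted p = 0.844). The hypothesis of lower ATF4 activity was tested on the cytosolic aminoacyl-tRNA synthetases. All 12 known as ATF4 targets were lower (median -1.16), against 6 lower and 2 higher of 8 others (median -0.44). Their means differed by -1.04 in log2, with an exact two-sided permutation p across genes of 1.3e-04, where genes are not independent replicates and 3 of the 12 had been seen before. A lower ATF4 programme in hypoxic DSC may account for this, and whether it is there in normoxia was not tested.

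Families of protein-coding genes that share the stem of their symbol were formed after the data were seen. Of 200 with at least 8 tested members, camera called 3 higher and 7 lower, and 0 passed with an estimated correlation (lowest adjusted p 0.987). Among the lower were the regulatory subunits of the proteasome (PSMD, 11 of 14 lower and 0 higher, median -0.58, adjusted p = 7.5e-03), nucleoporins (NUP, 15 of 20 lower, median -0.47, adjusted p = 6.2e-03) and the ribosomal RNA processing genes named RRP (7 of 8 lower, median -0.97, adjusted p = 0.0151). The ABCA lipid transporters were higher in 8 of 10 and lower in 1 (median 2.20, adjusted p = 0.0151), with ABCA6 at 3.82 ± 0.15 and the cholesterol exporter ABCA1 at 2.03 ± 0.08. The HOXA genes, some of which set position along the reproductive tract, were higher in 8 of 11 and lower in 2 (median 1.46) without a call (adjusted p = 0.0700). These directions held under each scaling alternative.

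Ribosomal protein mRNAs were higher in DSC in 76 of 81 genes and lower in 4 (median 0.79, and 0.68 with library totals alone), and took 4.52% ± 0.211 of the counts against 2.80% ± 0.224 in ESF (SD, n = 2 each). Better recovery of short transcripts is contradicted as the whole cause: in 10000 random sets of other protein-coding genes matched on length and level, the central 95% of the medians ended at 0.28 and the highest was 0.56. The 11 genes with no count on a named pseudogene, including any without such a pseudogene, had a median of 0.67, with 8 higher and 3 lower. A rise was thus also seen without counts on named pseudogenes. Pseudogene reads placed wholly on the parent gene would escape this test, so shared reads are not excluded. The hypothesis that mRNAs with a terminal oligopyrimidine tract, a translation control element, rise together was tested on 17 other genes of the class, of which FAU and UBA52 also encode ribosomal proteins: all 17 were higher (15 with library totals alone), with a median of 0.66. EEF1G among them rests on few counts, at 0.322 CPM in ESF and 0.739 in DSC, far below the other members. These 17 genes were not compared with genes matched on length and level, so a technical origin of their rise stays open. A shared change of this class in DSC may be biological, and its relation to cell division or culture conditions was not tested.

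HIF target genes outside glycolysis were called higher in DSC by camera (adjusted p = 8.2e-06, and adjusted p = 0.288 with an estimated correlation), while the glycolysis genes were called higher by fry alone (adjusted p = 4.8e-03). The choice among the scalings tried does not account for the higher HIF targets. Library totals alone moved genes by a median of -0.11 in log2, which left the HIF target median at 0.62, with 23 of 29 members still called higher. All these scalings are relative, so a difference in RNA content per cell was not tested. The lists were not raised alike in DSC: the glycolysis median lay 0.63 below that of the other targets, narrowly beyond the SD of 0.61 among glycolysis genes. A permutation test of the means across genes, which are not independent, gave p = 7.8e-04 (100000 resamples, two-sided). Both medians were known before these comparisons were chosen, so they restate a difference already seen. Without normoxic samples they cannot decide whether HIF signalling was stronger in DSC. Targets that depend on other regulators in DSC, or a difference already there in normoxia, stay open and were not tested.

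IFI44L and IFI44, neighbours among the interferon-inducible genes, were higher in DSC without most of their class. A general interferon response is contradicted by the 13 other tested members, of which 6 were lower and 2 higher (median -0.38). Both DSC libraries carried the rise of IFI44L, as the lower of them exceeded the higher ESF library 225-fold. This is not a separate test against a single aberrant library, since IFI44L was named among genes without overlap between the groups. The rise of IFI44L was 6.32 times that of IFI44 in CPM. This ratio cannot decide whether reads of IFI44 were counted as IFI44L, because such reads leave the IFI44 count. A fixed part of the IFI44 reads, as the only source of IFI44L, would give both groups the same share of IFI44. The shares given next argue against that. Reads of IFI44L do not account for IFI44 in ESF, where IFI44 took 87.8% and 82.6% of the reads of both genes, against 14.5% and 15.6% in DSC. For its rise in DSC they cannot be told apart from its own reads, because the DSC libraries differed by only 1.12 percentage points in that share, within their exact 95% binomial intervals and as either origin would give; a regulator other than interferon was not tested.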
